A study of Mus musculus with 7 samples.

How the data were processed

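RNA was measured by sequencing in GFP-positive cells sorted from cervical dorsal root ganglia of mouse embryos at embryonic day 11.5, per the labels' protocols. The Runx3-P2 allele carries GFP at the Runx3 locus and marks TrkC neurons, the precursors of proprioceptive sensory neurons. The 7 libraries fell into 3 heterozygotes and 4 homozygotes. The libraries were made from amplified cDNA and read as single-end sequence, per the labels' protocols.

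The raw count per gene and library was deposited by the authors. TopHat 1.4.0, HTSeq, DESeq2 1.2.8 and the genome build mm9 are named in the submitters' processing notes, without a role for each; the annotation and the strand setting are not given in the sources used here. The deposited normalized reads equalled the raw count divided by 1 factor per library and were not used in any test. The authors' deposited log2 fold changes and adjusted p-values, given as heterozygote over homozygote, were used only for comparison, with the sign turned. Whether those fold changes were shrunken is not given in the sources used here. The file headers call the heterozygotes WT. Of 29777 genes, 10416 had 0 counts in every library. A spreadsheet had turned 27 gene names into dates; these genes held 0.321% of the counts and were kept but not named. No coordinates are given, because the reference at hand has another build than the files. Old symbols are printed as in the files.

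As a check for a library deposited more than once, counts were compared between libraries of a genotype; every pair differed by more than sampling noise (chi-square per degree of freedom from 29.1 to 72). Total counts ranged from 11184237 to 13986835 per library. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 14040. Libraries were scaled by TMM in edgeR 4.0.16 under R 4.3.3. Genotypes were compared with edgeR's quasi-likelihood test (glmQLFit, non-robust, with that release's default quasi-dispersion, and glmQLFTest, two-sided), with heterozygotes as the reference and Benjamini-Hochberg adjustment. A gene was called at an adjusted p below 0.05. Standard errors were the log2 fold change divided by the square root of F. Values per library are CPM (the count scaled to the effective library size) after TMM.

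A total of 38 gene lists was written before the data were examined, and 37 had at least 3 tested members; the mitochondrially encoded list did not. Lists were tested with limma 3.58.1 camera at a preset correlation of 0.01, and again with an estimated correlation, which compare a list with the other genes. They were also tested with fry, which asks only whether the genes of a list move on balance in 1 direction. Genes named in the text were set by a rule written before the data were examined. It took Runx3, then up to 12 rises and 12 falls of largest size among called genes with mean log2 CPM of at least 1 and no overlap between genotypes. Where fewer than 5 qualified, it took the 5 smallest p in that direction with mean log2 CPM of at least 1. Predicted and unnamed models were left out. It added up to 4 called members of each list (or the 2 most abundant), and Ntrk2, Ntrk3, Etv1, Pvalb, Shox2, Maf, Ret, Runx1 and Cbfb; 1 further gene of that set is not reported here. Members called only by DESeq2 were chosen after the values were seen.

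The alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, other scalings and count filters, robust estimation, the label date as a covariate, a window of dates, leaving out technical genes and leaving out each library. The title of heterozygote library 1 gives month 1 and its source name month 11. Month 11 was used for the covariate and the window. The window, 27.10.13 to 23.12.13, left out homozygote libraries 1 and 3 and no heterozygote library. Those added afterwards were a likelihood ratio test, the adjusted quasi-dispersion that later edgeR releases use by default, the leukocyte list mean as a covariate, and leaving out heterozygote library 3 with homozygote library 3. The choice between the default and the adjusted quasi-dispersion was not written down beforehand. The default is reported as the main result because it was run first, and both counts are given.

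The steps were tested on simulated counts for these 14040 genes, in 3 sets with 200 changed genes each, drawn from genes with mean log2 CPM of at least 1. edgeR recovered 20% of genes changed 2-fold, 75.3% at 4-fold, 88.7% at 8-fold and 96% at 16-fold, and 6.5% of its calls were false. DESeq2 recovered 35.3%, 84.7%, 94.7% and 98.7%, and 22.4% of its calls were false. The adjusted quasi-dispersion was not simulated. Each gene was drawn on its own from a negative binomial distribution with edgeR's dispersions. The simulated counts held no correlated genes and no outlying library, so these rates may not hold for the real libraries. Ratios with 95% exact intervals cover counting error only.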

Results

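GFP-positive cells sorted from cervical ganglia as TrkC neurons were compared between embryos heterozygous and homozygous for the Runx3-P2 allele. The aim was to ask which genes depend on Runx3, a Runt-family transcription factor, in these neurons. GFP sits in the allele, so homozygotes carry it on both copies of the locus. Whether the gate collected the same cells in both genotypes was not tested. There were 3 heterozygote and 4 homozygote libraries, with 11184237 to 13986835 counts each. The design text speaks of pools of 4, and the labels do not say whether each library came from separate litters; p-values measure the spread between these libraries.

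Runx3 fell in the homozygotes, from 85.3 ± 15.7 CPM (SD, n = 3) to 9.17 ± 3.06 CPM (SD, n = 4). The counts were 862, 1088 and 1087 in the heterozygotes and 90, 148, 81 and 143 in the homozygotes. The log2 fold change was -3.22 ± 0.30 (SE; adjusted p = 0.00593, edgeR quasi-likelihood test). Counts per gene do not separate the transcripts of the P1 and P2 promoters. The call ended without heterozygote library 2 (adjusted p = 0.0885, edgeR) and without heterozygote library 3 (adjusted p = 0.0576, edgeR), at log2 fold changes of -3.14 and -3.12.

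Of 14040 genes tested, 7 changed: 5 fell and 2 rose, each at least 2-fold. Fam19a4 (now Tafa4), which encodes a secreted chemokine-like protein, fell from 214 ± 24.4 CPM to 13.3 ± 4.62 CPM (SD, n = 3 and 4), a log2 fold change of -4.01 ± 0.30 (SE; adjusted p = 0.00131, edgeR). It was the single gene called under all 21 alternative settings. Pcdh15, a protocadherin of hair-cell tip links, fell by 2.40 ± 0.27 on the log2 scale (adjusted p = 0.023, edgeR). Avil, the actin-binding protein advillin of sensory neurons, fell by 2.43 ± 0.33 (adjusted p = 0.0493, edgeR). Tub, the tubby protein, fell by 1.25 ± 0.16 (adjusted p = 0.0403, edgeR).

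The 2 genes that rose lay outside the rule for named genes and were picked after their values were seen. Gna14, a G protein alpha subunit, had 1 count summed over the heterozygotes and 395 over the homozygotes, a ratio of 279 (95% exact interval 49.8 to 11040). Papss2, an enzyme that makes the sulfate donor PAPS, had 4 against 329 counts, a ratio of 58.1 (interval 22.5 to 214). Both had an adjusted p of 0.0403 (edgeR).

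**Figure D1:**
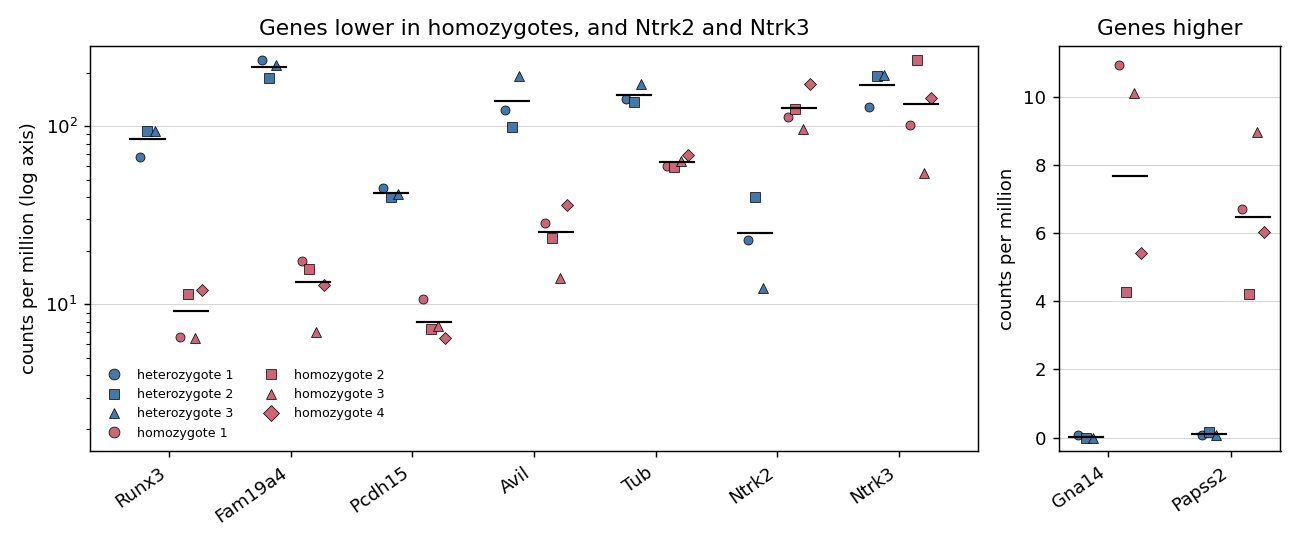
CPM in each library (points; bars are genotype means) of the genes that fell and of Ntrk2 and Ntrk3, on a log axis, and of the 2 genes that rose, on a linear axis. Runx3 averaged 85.3 CPM in heterozygotes and 9.17 CPM in homozygotes, and Ntrk2 25.2 and 127 CPM.

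No rise met the full rule, so the 5 with the smallest p among rises of mean log2 CPM of at least 1 are given; none passed the test. Gna14 and Papss2 had smaller p but lay below that level. Fgfr3, a fibroblast growth factor receptor, averaged 4.86 ± 2.43 CPM in heterozygotes and 30.4 ± 8.08 CPM in homozygotes (SD, n = 3 and 4; adjusted p = 0.0626, edgeR). The others were Csf2rb, the shared beta subunit of cytokine receptors (1 against 1065 counts, ratio 752, interval 135 to 29718), Dock8, Tnfaip8l2 and Samd9l. Their log2 fold changes were 5.75 ± 0.90 for Dock8, 4.52 ± 0.70 for Tnfaip8l2 and 4.81 ± 0.77 for Samd9l (adjusted p = 0.0626 for each, edgeR). Csf2rb, Dock8 and Tnfaip8l2 are known from blood cells, and the leukocyte list described with the other cell types was also higher by camera at the preset correlation and did not pass with an estimated correlation (adjusted p = 0.523).

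Among neurotrophin receptors, Ntrk2 (TrkB) averaged 25.2 ± 14.1 CPM in heterozygotes and 127 ± 32.3 CPM in homozygotes (SD, n = 3 and 4), without overlap. Its log2 fold change of 2.33 ± 0.38 missed the threshold (adjusted p = 0.0626, edgeR) and passed with DESeq2 (adjusted p = 6.73e-08). Ntrk3 (TrkC) differed by less than the spread between libraries, at -0.35 ± 0.40 (adjusted p = 0.806, edgeR). The list of neurotrophin and GDNF receptors and ligands had 0 of 17 members called over all genes by edgeR. Adjusted over the list alone, 3 were higher and 2 lower. Gfra2, a GDNF-family receptor, was at 1.39 ± 0.33 and Gfra3, the artemin receptor, at -1.38 ± 0.28 on the log2 scale.

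The genes always named for these neurons did not pass the test. Etv1, a transcription factor of proprioceptive neurons, had a log2 fold change of -0.35 ± 0.35 and Shox2, a factor of mechanoreceptors, of -0.24 ± 0.27. Maf was at 0.54 ± 0.36, Ret at -0.47 ± 1.46 and Runx1 at 0.23 ± 0.44. Cbfb, the partner subunit of Runx proteins, was at -0.34 ± 0.23. Pvalb had 22, 19 and 20 counts in the heterozygotes and 0, 2, 0 and 14 in the homozygotes, a log2 fold change of -2.33 ± 1.35 (adjusted p = 0.54, edgeR).

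The list of nociceptive neuron genes was lower in the homozygotes, with a median log2 fold change of -1.07 over 14 tested members (camera adjusted p = 1.55e-07). With an estimated correlation the call was lost (adjusted p = 0.462). The mean of the leukocyte list described with the other cell types was higher in all 4 homozygote libraries than in any heterozygote library; with this mean as a covariate, added after seeing the data, the median was -0.16 (camera adjusted p = 0.603). Without both heterozygote library 3 and homozygote library 3, also added after seeing the data, it was -0.68 and the call was kept. No member was called over all genes by edgeR; 8 had an unadjusted p below 0.05, and DESeq2 called 1 higher and 6 lower. Adjusted over the list alone, 6 fell and 1 rose. Calca and Calcb, which encode CGRP peptides, were at -3.82 ± 0.77 and -3.68 ± 0.81; reads may be shared between these near-copies. Prdm12, a transcription factor of nociceptors, was at -1.59 ± 0.27. The exception, Sst (somatostatin), was at 15.9 ± 9.11 CPM in heterozygotes and 126 ± 90 CPM in homozygotes (SD, n = 3 and 4). The broad sensory neuron list was lower as well, with a median of -0.32 over 29 members, 1 of which, Avil, was called by edgeR (camera adjusted p = 7.28e-06; adjusted p = 0.689 with an estimated correlation). Its median was 0.11 with the leukocyte covariate (camera adjusted p = 0.809), and -0.15 without both libraries 3 and -0.11 in the window of dates, with the call kept. Adjusted over the list alone, 4 fell.

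The list of cadherins and adhesion molecules was lower, with a median of -0.46 over 63 members and 1 called, Pcdh15 (camera adjusted p = 3.62e-06; adjusted p = 0.462 with an estimated correlation). Its median was -0.0178 with the leukocyte covariate (camera adjusted p = 0.809). The call was kept at -0.23 without heterozygote library 3 and at -0.14 without both libraries 3 (camera adjusted p = 0.043). Adjusted over the list alone, 5 fell. Sodium, calcium and HCN channel genes had a median of -0.26 over 29 members (camera adjusted p = 0.0024; adjusted p = 0.689 with an estimated correlation), with 3 lower adjusted over the list alone, among them Scn7a at -1.57 ± 0.32 and Scn10a at -1.66 ± 0.37. Medians over left-out libraries ran from -0.43 to -0.15, and the call ended in the window of dates, without both libraries 3 and with the leukocyte covariate. Potassium channel genes had a median of -0.48 over 48 members (camera adjusted p = 0.000625; adjusted p = 0.462 with an estimated correlation), with 1 lower adjusted over the list alone. That call ended without both libraries 3 (-0.42; camera adjusted p = 0.0881) and with the leukocyte covariate (-0.14; camera adjusted p = 0.603). The Runx family list was lower (median -0.32 over 10 members; camera adjusted p = 0.000764; adjusted p = 0.462 with an estimated correlation), and Runx3 was its single called member. Runx3 is also the targeted gene, so the camera p of this list is partly set by the design. Of the list's members, 9 had a negative log2 fold change and 1 a positive one. The list's median was -0.15 without heterozygote library 3 and -0.21 without homozygote library 3. The call ended without both (-0.0422; camera adjusted p = 0.082) and with the leukocyte covariate (0.0658; camera adjusted p = 0.603).

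Of the lists of other cell types, 4 were higher in the homozygotes by camera at the preset correlation, and none with an estimated correlation. The leukocyte list had a median log2 fold change of 3.93 over 16 tested members (camera adjusted p = 2.71e-14; adjusted p = 0.523 with an estimated correlation). No member was called over all genes by edgeR, 14 had an unadjusted p below 0.05, and DESeq2 called 10. Adjusted over the list alone, 14 rose. The call was kept without homozygote library 3 (2.47) and without both libraries 3 (2.01). Tyrobp, an adaptor of myeloid receptors, averaged 6 ± 4.89 CPM in heterozygotes and 113 ± 132 CPM in homozygotes (SD, n = 3 and 4). The list mean was 3.01, 2.88 and -0.59 log2 CPM in the heterozygotes and 3.93, 4.81, 7.45 and 5.16 in the homozygotes. Spinal cord (median 1.70; adjusted p = 0.689 with an estimated correlation), mesenchyme (0.56; adjusted p = 0.689) and skeletal muscle markers (1.65; adjusted p = 0.689) were higher by camera as well. Spinal cord medians over left-out libraries ran from 0.97 to 2.77 with the call kept; it ended in the window of dates (1.02; camera adjusted p = 0.0533), without both libraries 3 (0.67; camera adjusted p = 0.297) and with the leukocyte covariate (0.0313; camera adjusted p = 0.603). The mesenchyme call ended without heterozygote library 3 or without homozygote library 1, 2 or 3 (medians over left-out libraries 0.24 to 1.08). The muscle call ended without heterozygote library 2 or 3 or without homozygote library 2 or 3 (0.80 to 2.10). Both calls also ended with the date covariate, without both libraries 3 and with the leukocyte covariate. The mesenchyme call ended as well with DESeq2 and in the window of dates, and the muscle call with limma-voom and the stricter filter. Endothelial, erythroid and sympathetic neuron lists did not pass (camera adjusted p = 0.247 for each). Neural crest and glial markers had a median of -0.26 (camera adjusted p = 0.588).

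Cell cycle genes were higher, with a median of 0.45 over 45 members (camera adjusted p = 5.84e-07; adjusted p = 0.689 with an estimated correlation). No member was called by edgeR, 12 had an unadjusted p below 0.05, and DESeq2 called 7, all higher, Mcm3 (1.47 ± 0.34) among them. Adjusted over the list alone, 0 passed. The median was 0.22 in the window of dates and 0.30 without homozygote library 3, with the call kept. It ended without both libraries 3 (0.15; camera adjusted p = 0.151) and with the leukocyte covariate (-0.0301; camera adjusted p = 0.915). Histone (median 0.38), ribosomal protein (0.22) and Hox genes of paralogue groups 6 to 13 (0.43) were also higher by camera (adjusted p = 0.0369, 0.00748 and 0.0411). Each had an adjusted p of 0.689 by camera with an estimated correlation. All 3 turned in camera direction with the leukocyte covariate, and all 3 calls ended in the window of dates, without heterozygote library 3 and without homozygote library 3; the histone call also ended without heterozygote library 1 and the Hox call without homozygote library 1. The histone and Hox calls also ended with the date covariate, and the Hox call with DESeq2. Medians over left-out libraries ran from 0.23 to 0.60, 0.13 to 0.30 and 0.07 to 0.82. Proprioceptive (camera adjusted p = 0.588) and mechanoreceptive neuron lists (camera adjusted p = 0.198) did not pass. Of 19 proprioceptive members, edgeR called 1 lower, and DESeq2 called 2 higher and 2 lower. Runx3, the targeted gene, is among the genes edgeR called lower, so this fall may be set by the design. The DESeq2 rises were Chodl (2.22 ± 0.60) and Chad, with 0 counts in every heterozygote library and 53, 27, 64 and 25 in the homozygotes. Of 14 mechanoreceptive members, edgeR called 0, and DESeq2 called 3 higher and 1 lower.

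**Figure D2:**
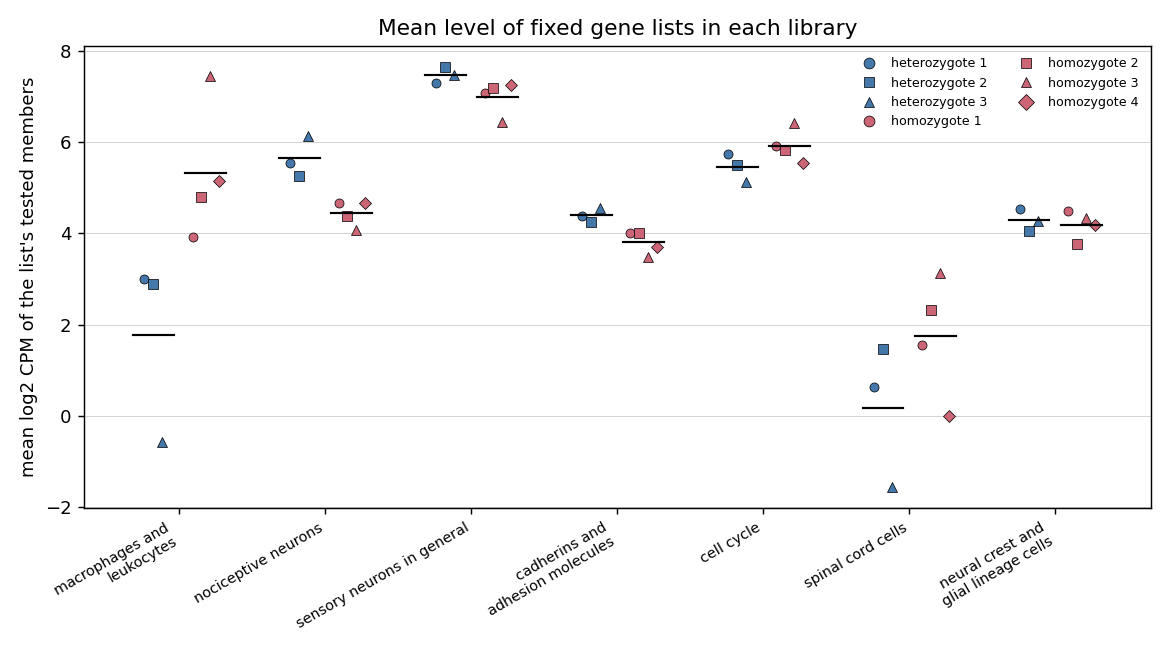
Mean log2 CPM of the tested members of 7 gene lists in each library (points; bars are genotype means). Homozygote library 3 had the highest leukocyte mean (7.45) and heterozygote library 3 the lowest (-0.59).

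The first principal component of the 500 most variable genes held 63% of the variance. Its ends were heterozygote library 3 (-68.3) and homozygote library 3 (65.9). The other heterozygote libraries lay at -25.3 and -29.3 and the other homozygote libraries at 19.6, 20.6 and 16.7. The component thus also separated the genotypes. With heterozygote library 3 and homozygote library 3 left out, 12 genes were called by edgeR, 2 of the 7 among them.

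DESeq2 on the same counts called 719 genes, 523 higher and 196 lower, 604 of them at least 2-fold. The authors' deposited adjusted p was below 0.05 for 611 genes, and 563 genes were called by both. The authors' deposited table lists 464 genes at an adjusted p below 0.05 and at least 2-fold, 338 higher and 126 lower in homozygotes. The 604 and the 464 rest on fold changes that differ for genes with low counts. All 7 genes called by edgeR were on the authors' list. All 464 moved in the same direction here with an unadjusted p below 0.05, and 86 had an adjusted p below 0.1 by edgeR; both rest on the same libraries. The authors' deposited table gave Ntrk2 a log2 fold change of 2.13 and Runx3 one of -3.00. Among genes tested, 926 were higher and 811 lower without overlap between genotypes, 12.4% against 5.71% by chance.

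The count of 7 depended on the test and the libraries. edgeR's adjusted quasi-dispersion, added after the count of 7 was seen, called 61 genes (25 higher, 36 lower). Of the 7 genes, 6 were kept and Gna14 was lost. In the main fit 1773 genes had an unadjusted p below 0.05 (edgeR) against 702 by chance. In fits added afterwards the number was 1066 without both libraries 3 and 638 with the leukocyte covariate. That covariate differed by genotype, so it removes part of any genotype effect. Genes varied together, so the number reached by chance can lie far from 702. Leaving out 1 library gave from 1 gene (without heterozygote library 2 or 3) to 27 genes (without homozygote library 3), and Pcdh15, Avil, Tub, Gna14 and Papss2 were each called in at most 2 of these 7 fits.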

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

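The values of the real split were known when the other splits were fitted. The splits of the adjusted quasi-dispersion and of both camera tests, and all tests of explanations for the leukocyte and nociceptive genes, were chosen only after those results were seen.

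All 35 ways to split the 7 libraries into 3 and 4 were fitted. The real split called 7 genes with edgeR and no other more than 1, so 1 of 35 gave as many; the same held for the 2 higher, the 5 lower and the 7 changed at least 2-fold. A share of 1 in 35 is the smallest the design allows. These counts describe the same 7 genes, among them Runx3, the targeted gene, so chance is not firmly excluded. With DESeq2 the real split called 719 genes and the next 394, and with the adjusted quasi-dispersion 61 and 1, again 1 of 35 in each. DESeq2's 394 came with homozygote libraries 2, 3 and 4 on one side, a split that keeps most of the genotype contrast. The like splits gave 368 with homozygote libraries 1, 2 and 3 on one side and 194 with 1, 3 and 4. Homozygote libraries 1, 2 and 4, without library 3, gave 15.

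Leukocyte genes were higher in the homozygotes. Chance cannot be excluded for the camera p of this list: 2 of 35 splits gave one as small, 7.32e-16 in the real split and 3.08e-21 with homozygote libraries 2, 3 and 4 on one side. Homozygote library 3 alone is argued against, since the list's median stayed at 2.47 without it. A lower share of neurons that raised every other type alike is only weakly argued against. The leukocyte mean rose by 2.59 more than the mean of 6 other non-neuronal lists (log2, exact two-sided permutation p = 0.0286, the smallest possible). But the leukocyte list was picked after its rise was seen, and the endothelial and erythroid lists had 3 and 5 tested members. The list's members varied together within genotypes (median correlation 0.897, against 0.141 at the 95th percentile of 1000 matched random sets). Those sets were matched on mean expression only, so any genes that vary together would stand out. Leukocytes among the sorted cells may contribute, but this correlation cannot tell them apart from genes changing together inside the neurons. A change inside the neurons, the effect of genotype, was not tested and stays open. The GFP gate reads the Runx3 locus, which leukocytes can also use.

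Nociceptive neuron genes were lower in the homozygotes. For the camera p, 1 of 35 splits was as small (8.36e-09, next 1.97e-07). That is the smallest share the design allows, for a list picked after its p was seen, and the call was lost with an estimated correlation (adjusted p = 0.462), so chance is not firmly excluded. Homozygote library 3 alone is argued against, as the median was -0.92 without it. A lower share of sensory neurons cannot be told apart: the list fell by 0.725 more than the sensory neuron list (exact two-sided permutation p = 0.0571). The genotype effect inside the neurons was not tested and stays open.

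Among 191 genes and lists, 7 had 1 homozygote library far from the other 3, where chance gives about 1 in 20, or 9.6. The gap over the range was 0.848 for Cd33, 0.895 for Csf2rb, 0.934 for P4ha2, 0.83 for Scn3b, 0.937 for the erythroid list and 0.888 for the ribosomal protein list, all in homozygote library 3, and 0.836 for Hoxc5 in homozygote library 1.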

How the results depend on the processing

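The date covariate, the scalings, the filters, the other tests and the left-out libraries were chosen before the data were examined; the fits marked as added were chosen after seeing the data. No paired analysis was possible because the labels number no libraries and no date is shared between genotypes.

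Calls are given as total, higher, lower and at least 2-fold, then those on the authors' deposited list. DESeq2 gave 719, 523, 196, 604 and 442. No filter gave 80, 48, 32, 80 and 77, and the stricter filter 65, 37, 28, 65 and 61. The date covariate gave 3, 0, 3, 3 and 3, with month 11 for heterozygote library 1, whose title gives month 1. limma-voom called 0 genes higher, with 1654 at an unadjusted p below 0.05. Leaving out each library gave 1 to 27 called, 0 to 14 higher, 1 to 13 lower, 1 to 27 at least 2-fold and 1 to 25 on the authors' list. Of the added fits, edgeR's adjusted quasi-dispersion gave 61, 25, 36, 61 and 57, the likelihood ratio test 580, 416, 164, 525 and 399, and the leukocyte covariate 1, 0, 1, 1 and 1. Leaving out heterozygote library 3 and homozygote library 3 gave 12, 9, 3 and 12. The cause was not tested. The adjusted quasi-dispersion is the default of later edgeR releases, so the count changes with the release installed. In the median-of-ratios, upper-quartile, robust and left-out-gene fits the 7 genes were kept. The window of dates called 10 genes and kept 3 of the 7, without Avil, Gna14, Papss2 and Tub. The window left out homozygote libraries 1 and 3, so an effect of date cannot be told apart from the loss of these libraries.

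Runx3 stayed lower in every fit, from -3.38 to -2.85. Without each library in turn it ranged from -3.38 to -3.07; it passed the threshold in 18 of 21 fits and missed it without heterozygote library 2, without heterozygote library 3 and with the leukocyte covariate (-2.92, adjusted p = 0.593, edgeR). The nociceptive, leukocyte, sensory neuron and adhesion lists kept their camera calls in 17 of 19 alternatives, losing them with the leukocyte covariate and an estimated correlation. Every other alternative used the preset correlation of 0.01, so kept calls do not measure that choice. The estimates were 0.235, 0.888, 0.386 and 0.0767 for these lists. For each of the leukocyte and nociceptive lists, preset camera also gave an unadjusted p below 0.05 in most of the other splits. With heterozygote library 2 and homozygote libraries 2 and 3 on one side, camera p was 1.66e-08 for the leukocyte list and 1.59e-05 for the nociceptive list. With heterozygote library 1 and homozygote libraries 3 and 4 the values were 4.07e-14 and 0.0665. With heterozygote libraries 1 and 3 and homozygote library 4 they were 7.85e-07 and 3.61e-07. The camera calls were kept in 11 of 19 for histone, 13 for ribosomal protein and 10 for Hox genes of paralogue groups 6 to 13. They were kept in 9 each for mesenchyme and muscle genes. The robust, likelihood ratio and adjusted quasi-dispersion fits are not counted, because they leave camera unchanged. Nor is fry, which asks whether a list moves on balance, without comparing it with other genes; its adjusted p was 0.174 for the nociceptive list and 0.389 for the leukocyte list. Several lists without a call in the report had medians of either sign over left-out libraries, such as the proprioceptive (-0.0992 to 0.58) and erythroid lists (-0.65 to 3.49). Lists with a call there turned camera direction in added fits only. The mesenchyme median was 0.11 without both libraries 3, opposite in camera's direction. With the leukocyte covariate the medians were -0.0301 for cell cycle, -0.83 for mesenchyme, 0.0313 for spinal cord, -0.0353 for ribosomal protein and -0.15 for histone genes. For Hox genes of paralogue groups 6 to 13 the median was -0.0611. All 6 turned in camera direction. The medians were -0.16 for nociceptive, -0.0178 for adhesion, 0.11 for sensory neuron and 0.0658 for Runx family genes, none called. This covariate itself differed by genotype (3.01, 2.88 and -0.59 against 3.93, 4.81, 7.45 and 5.16), so the fit removes part of any genotype effect. Low counts limit Gna14, Papss2 and Csf2rb, near 0 in heterozygotes.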

Other observations

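Several genes outside the comparisons' lead findings moved without overlap between genotypes, though none passed edgeR's test over all genes. Of the retinoic acid list, Dhrs3, a retinaldehyde reductase, averaged 35.4 ± 18.2 CPM in heterozygotes and 181 ± 123 CPM in homozygotes (SD, n = 3 and 4), and Rara, a retinoic acid receptor, 17.4 ± 1.74 and 35.8 ± 12.4 CPM. Stra6, a retinol transporter, went the other way, at 168 ± 47.2 and 71.1 ± 25 CPM. The list of 16 members missed the threshold (camera adjusted p = 0.0548). The Notch ligand Dll1 was at 12.9 ± 4.5 and 36.6 ± 7.53 CPM. Of the apoptosis genes, Hrk was at 48.1 ± 17.5 and 18.8 ± 7.03 CPM, and Pmaip1 at 2.35 ± 1.71 and 13.7 ± 11.9 CPM. Pmaip1 reached 31.2 CPM in homozygote library 3 and 5.91 to 10.8 CPM in the other homozygote libraries.

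The remaining lists did not pass camera in the main fit. The adjusted p was 0.97 for neurotrophin receptors and ligands, 0.247 for neurogenesis, 0.83 for axon guidance, 0.798 for apoptosis, 0.653 for TGF-beta and BMP, 0.322 for Wnt and 0.258 for neuropeptides. It was 0.247 for endothelial, erythroid and sympathetic markers, 0.587 for dissociation stress, 0.658 for hypoxia and glycolysis, 0.928 for cholesterol synthesis and 0.726 for sex-linked genes. It was 0.0548 for mechanosensitive and related channels, 0.605 for glutamate receptors and 0.452 for GABA and glycine receptors. It was 0.292 for Hox genes of paralogue groups 1 to 5 and 0.302 for clustered protocadherins. Of 19 camera alternatives, the mechanosensitive list was called in 9 and the retinoic acid list in 3.

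Xist counts were 3221, 2084 and 2 in heterozygote libraries 1 to 3 and 778, 1, 2662 and 2 in homozygote libraries 1 to 4. The Y-linked Eif2s3y had 495 to 2893 counts in every library.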
